A study of Mus musculus with 3 samples.

How the data were processed

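Notch2 ChIP-seq was performed on crosslinked embryonic kidneys of the mouse, per the labels' protocols, and libraries were made with a commercial ChIP-seq kit for Illumina sequencing. The 3 samples were 2 Notch2 immunoprecipitations, numbered 1 and 2 by the labels, and 1 input. Bowtie, SAMtools, HOMER and the mm9 build are named in the submitters' processing notes, without versions or roles. The settings of peak calling, the use of the input and the filters applied are not given in the sources used here. The authors deposited 1 peak list for each immunoprecipitation, so that peaks were listed per sample and not on pooled samples. Each deposited list held 3 columns, the chromosome, the start and the end of each peak in base pairs, with no score, signal or count. Positions on chromosome 7 reached 7.15 Mb beyond the last gene of a GRCm38 gene table, so the coordinates are not those of GRCm38. The stated build mm9 was kept, and positions are given counted from 1.

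Some rows occurred more than once within a list. Replicate 1 had 28893 rows, of which 242 repeated another row exactly, and replicate 2 had 13065 rows, of which 480 did. Each peak was counted once. No other peaks of the same list overlapped. Read numbers do not enter these lists, and the precision of a share is given by its 95% Wilson interval, which covers counting error only. Ratios of numbers of peaks have exact intervals from the binomial distribution. A peak caller run on a deeper or more enriched library lists more and weaker peaks, so that numbers of peaks and shares of shared peaks depend on depth and on the caller's threshold.

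Peaks were called shared when they overlapped by at least 1 bp. The number of shared replicate 2 peaks was compared with 1000 random placements of the replicate 2 peaks within the same chromosomes, between the outermost peaks of both lists, with a one-sided permutation p. Such placements do not account for chromatin accessibility or mappability, so that the ratio measures agreement against an even genome. Peak width stood in for strength because the lists hold no score, as fixed before the data were examined, and 4 classes were formed by mean rank, so that all 500 bp peaks fell in the last class. Place in the list as a second ranking and peak densities over the autosomes and the X chromosome were chosen after the data were seen. Shares in the first and last class were compared by a two-sided permutation test with 100000 resamples, and correlations have permutation p-values with 100000 resamples. Clusters joined peaks whose edges lay within 12500 bp. Protein-coding genes per chromosome were counted in a RefSeq gene table of GRCm38, with 21627 genes on the 20 chromosomes, by chromosome alone and without use of its positions.

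Regions to be named were set by a rule fixed before the data were examined, which took the 15 shared peaks of best mean rank by width and the 3 widest peaks of each replicate without a counterpart. The planned comparisons with promoters, gene lists and the RBPJ sequence motif need an annotation or sequence of mm9 and were not run. Alternatives were tried for the overlap criterion, the part of each list used, the placement, the treatment of clusters and repeated rows, and the distance for joining clusters.

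Overlap counts and the placement test were tested on simulated data. In 20 simulated replicate 2 lists, 3000 planted peaks each were centred on replicate 1 peaks. All 3000 were found, as this design ensures, and the counts equalled those of bedtools in 20 of 20. The number planted was estimated at 2974 to 3025 after subtraction of the placements. Of 40 unrelated lists, 0 gave a p under 0.05, and of 100 unrelated pairs of rankings 3 did. The unrelated lists were drawn evenly within chromosomes, as the placements are, so they check the computation only. They do not show how the test behaves for unrelated lists that are clustered or share accessible chromatin. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1.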

Results

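Genome-wide occupancy of Notch2 was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole mouse embryonic kidney at stage E16.5. Notch2 is a receptor of the Notch family. On activation its intracellular part is released by cleavage and acts in the nucleus with the DNA-binding protein RBPJ, and in the kidney the pathway takes part in the patterning of the forming nephron. Chromatin fragments bound by an anti-Notch2 antibody were sequenced from 2 replicate samples, and 1 input sample of kidney chromatin accompanied them. Both replicates had a list of called peaks, that is, of regions with an excess of sequenced fragments. The lists gave positions on the mm9 build of the mouse genome and no peak height, fold enrichment, score or p-value. The read depth behind each list is therefore unknown, and the input was not analysed here as a library of its own. The labels do not say whether the replicates came from separate litters or pools of kidneys, so that the comparisons measure the difference between these samples, which may be technical. No annotation of the mm9 build was used here, and regions are given by position without genes.

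The series asks where Notch2 lies on the genome of the embryonic kidney. Replicate 1 had 28651 peaks and replicate 2 had 12585, a ratio of 2.28. The peaks of replicate 1 covered 21.8 Mb and had a median width of 637 bp, with an interquartile range of 500 to 847 bp. Those of replicate 2 covered 8.41 Mb and had a median width of 626 bp, with an interquartile range of 500 to 722 bp. The narrowest peaks measured 500 bp in both lists, and these made up 31.8% of replicate 1 and 47.9% of replicate 2. The next width in either list was 625 bp. The widest peak measured 4694 bp in replicate 1 and 4101 bp in replicate 2. Peaks lay on the 19 autosomes and on the X chromosome in both replicates.

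The first comparison asked how far the replicates marked the same sites. Most regions found in replicate 2 were found again in replicate 1, and the reverse held for a minority. Of the 12585 peaks of replicate 2, 9504 overlapped a replicate 1 peak by at least 1 bp, a share of 75.5% (95% Wilson interval 74.8 to 76.3%). Of the 28651 peaks of replicate 1, 9469 overlapped a replicate 2 peak, a share of 33.0% (95% Wilson interval 32.5 to 33.6%). The remaining 19182 peaks of replicate 1 and 3081 peaks of replicate 2 had no counterpart. These intervals cover counting error only. When both lists were limited to the same number of peaks, 46.4% of the replicate 2 peaks were shared with the widest peaks of replicate 1 and 55.7% with the first peaks of replicate 1 in list order, so that the share of 75.5% depended on the length of the longer list.

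Random placement of the replicate 2 peaks within their chromosomes gave an overlap of 211 ± 14.6 peaks (SD, 1000 placements) and at most 253. The observed number was 45.0 times the mean of the placements (one-sided permutation p = 0.000999, the smallest that these placements can give). Positions matched closely within shared regions. Among 9442 pairs of peaks that were each other's best overlap, the centres lay a median of 81 bp apart, and in 88.4% of pairs they lay within 250 bp. Selection for overlap by itself brings centres near, so these 2 values have no baseline of their own. Centres within 100 bp were found for 5540 replicate 2 peaks, 188 times the mean of placements, against 45.0 times for any overlap. The replicate 1 peak was the wider one in 66.7% of pairs and the narrower one in 22.6%. After the whole replicate 2 list had been shifted by 1 kb, the number of overlapping peaks was 21.0% of the unshifted number, and after a shift of 10 kb it was 6.44%, the mean of both directions. These numbers count any peak of the shifted list.

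**Figure D1:**
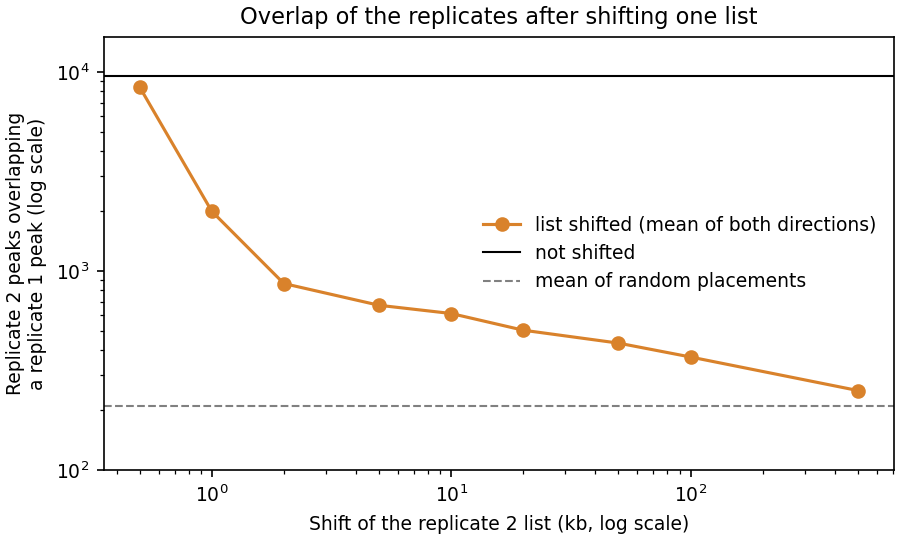
Number of replicate 2 peaks that overlap a replicate 1 peak (vertical axis, log scale) after the whole replicate 2 list was moved by the distance on the horizontal axis (kb, log scale). Points are the mean of both directions, the solid line is the unshifted overlap of 9504 peaks and the dashed line is the mean of 1000 random placements (211 peaks). The overlap falls steeply within 2 kb and approaches the dashed line at 500 kb.

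Agreement between the replicates rose with the width of the peaks. In replicate 1, 52.5% of the widest of 4 width classes (848 bp and wider; 95% Wilson interval 51.3 to 53.7%) were shared, against 16.2% of the 500 bp peaks (15.5 to 17.0%). In replicate 2 the shares were 92.0% of the widest class (722 bp and wider; 91.0 to 92.9%) and 63.3% of the 500 bp peaks (62.1 to 64.5%). The difference was 36.3 percentage points in replicate 1 and 28.7 in replicate 2 (two-sided permutation p = 1e-05 for both, the smallest that the permutations can give). The test treated peaks as independent although many are clustered, and it does not measure variation between samples. The intermediate classes did not form an even gradient, and in replicate 1 they reached 33.4% (637 to 847 bp) and 35.2% (625 to 636 bp). Widths of the paired peaks were correlated across peaks (Spearman rho = 0.42, permutation p = 1e-05, 9442 pairs, which are not independent replicates).

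The order of the files, which the sources used here do not describe, separated shared from unshared peaks more than width did in replicate 1. There 69.2% of the first of 4 classes by list order were shared, against 52.5% of the widest class. In replicate 2 these shares were close, at 93.3% and 92.0%. Its last classes differ in size, with 3147 peaks by list order and 6028 by width, and are not directly comparable. All of the first 100 peaks of replicate 1 and all of the first 100 of replicate 2 overlapped a peak of the other list. Among the first 1000 peaks the shares were 93.3% in replicate 1 and 95.7% in replicate 2. In the last 25% of each list they were 9.91% in replicate 1 and 56.7% in replicate 2. The places of paired peaks in the lists had a Spearman rho of 0.61 (permutation p = 1e-05, over pairs that are not independent replicates).

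**Figure D2:**
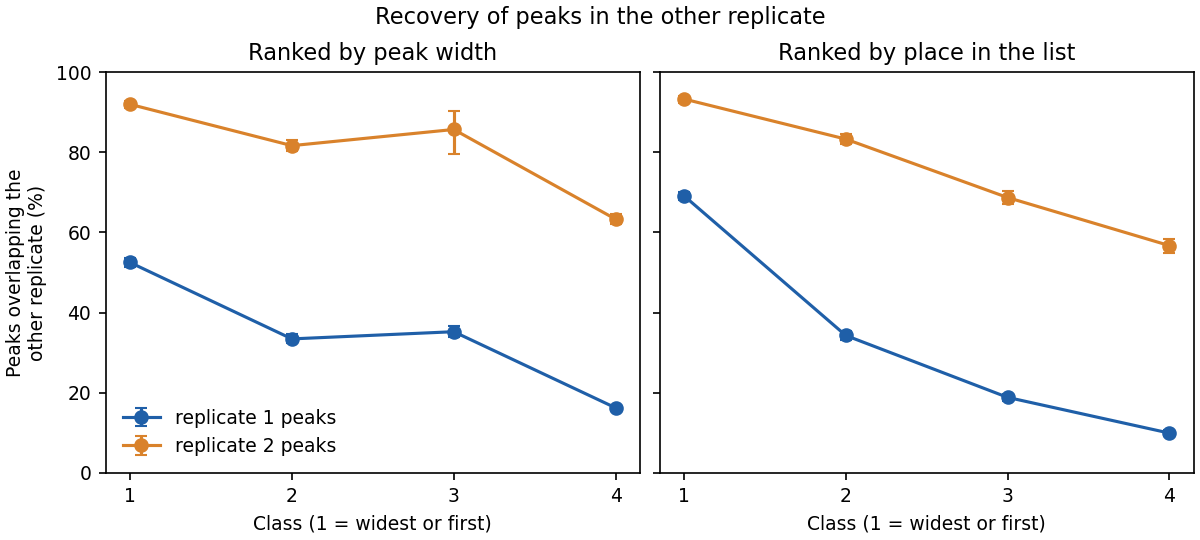
Percentage of peaks that overlap a peak of the other replicate (vertical axis) in each of 4 classes of the list (horizontal axis, class 1 is the widest or first), ranked by width on the left and by place in the list on the right. Bars are 95% Wilson intervals, and by width all 500 bp peaks are in class 4. Shares fall from 52.5% to 16.2% in replicate 1 and from 92.0% to 63.3% in replicate 2 by width, and without interruption by place.

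The 15 shared regions of best mean rank by width lay on 8 chromosomes and measured 2763 to 4486 bp in replicate 1 and 1822 to 3519 bp in replicate 2. The first was on chromosome 8 from 27461089 to 27465574 in replicate 1 and from 27461977 to 27465495 in replicate 2, and it had rank 3 by width in both lists. The second, on chromosome 3, ran from 53095846 to 53099515 in replicate 1 and measured 3670 bp there and 3511 bp in replicate 2. A further region of chromosome 3 ran from 82078257 to 82081882 and measured 3626 bp in replicate 1 and 3055 bp in replicate 2. Chromosome 8 held regions from 129257113 to 129261264 and from 64462499 to 64466076, with widths in replicate 1 of 4152 and 3578 bp and in replicate 2 of 2437 and 2361 bp. On chromosome 2 there were regions from 115336937 to 115340051 (3115 bp in replicate 1 and 2989 bp in replicate 2), from 75935539 to 75938566 (3028 and 2562 bp) and from 75905872 to 75908783 (2912 and 2741 bp). Chromosome 14 held regions from 23631960 to 23634926 (2967 and 2700 bp) and from 23627536 to 23630593 (3058 and 2271 bp). The remaining regions, with positions from replicate 1, were on chromosome 12 from 25780964 to 25783937, chromosome 7 from 78543781 to 78546543, chromosome 16 from 30063912 to 30067016, chromosome 5 from 44932638 to 44935487 and chromosome 3 from 37833989 to 37837809. All 15 were within the first 765 peaks of replicate 1 and the first 431 of replicate 2 in list order.

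Wide peaks without a counterpart were fewer in replicate 2. The widest in replicate 1 were on chromosome 2 from 26447887 to 26451935 (4049 bp), chromosome 9 from 107883814 to 107887802 (3989 bp) and chromosome 15 from 93540827 to 93544757 (3931 bp). The nearest replicate 2 peaks lay 8.36, 238 and 60.5 kb away. In replicate 2 the widest were on chromosome 6 from 50615154 to 50618102 (2949 bp) and from 50933431 to 50935535 (2105 bp), and on chromosome 13 from 5712485 to 5714402 (1918 bp). Of these, the second lay 0.965 kb and the third 3.06 kb from a replicate 1 peak, and the first 52.5 kb from one. Unshared peaks numbered 3400 of 7159 in the widest class of replicate 1 and 252 of 3147 in that of replicate 2. These classes began at 848 bp and 722 bp. Replicate 1 was checked against 12585 peaks and replicate 2 against 28651, so the longer list alone could leave fewer unshared peaks in replicate 2.

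Most peaks stood alone, and a small part gathered in large clusters. With peaks joined when their edges lay within 12500 bp, 68.4% of the 9469 shared peaks of replicate 1 had no other shared peak beside them, as did 52.4% of all peaks of replicate 1 and 63.4% of replicate 2 within their own lists. A further 197 shared peaks (2.08%) formed 34 clusters of 5 or more peaks, against a mean of 0.06 and at most 1 in 100 random placements. The count depended on the distance for joining, with 2 such clusters at 5 kb and 99 at 25 kb. Such clustering was not particular to shared peaks. All peaks of replicate 1 formed 329 clusters of this size (7.26% of peaks, mean of 11.3 in placements). Those of replicate 2 formed 59 (2.88%, mean of 0.16). In all, 8 clusters held 7 or more shared peaks, a limit chosen after the values were seen, and they lay on chromosomes 2, 3, 7, 14 and 16. Chromosome 7 held 3 of them, from 78359366 to 78395030 (8 shared peaks), from 78513234 to 78556912 (9 shared peaks) and from 78601800 to 78646254 (7 shared peaks). Chromosome 2 held a cluster from 75905872 to 75961310 with 9 shared peaks and one from 110019821 to 110067338 with 7. Chromosome 3 held one from 29973385 to 30012866 with 9 shared peaks, and chromosome 16 one from 30050537 to 30082613 with 8. On chromosome 14 a cluster of 7 shared peaks ran from 23396404 to 23453457. The cluster with most peaks in replicate 1 was on chromosome 6 from 52110760 to 52221425, a stretch of 111 kb with 29 peaks in replicate 1 and 16 in replicate 2, and 11 of the 29 were shared.

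**Figure D3:**
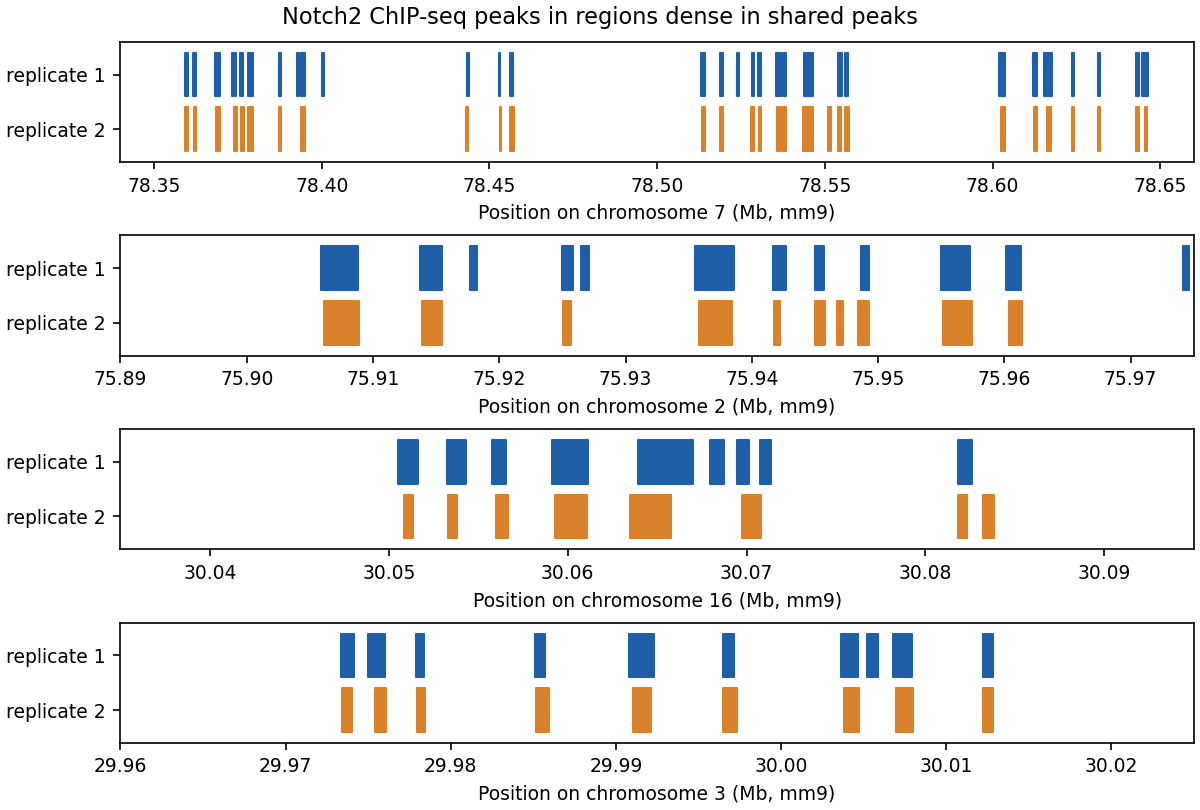
Positions of Notch2 ChIP-seq peaks (boxes, drawn to scale) of replicate 1 and replicate 2 in 4 windows of the mm9 genome, with the position in Mb on each horizontal axis. The window on chromosome 7 holds 3 clusters with 8, 9 and 7 shared peaks, and the windows on chromosomes 2, 16 and 3 hold clusters with 9, 8 and 9. Most boxes of replicate 2 lie below a box of replicate 1.

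The distribution over chromosomes was similar in rank between the replicates. Numbers of peaks per chromosome had a Pearson r of 0.93 (permutation p = 1e-05) and a Spearman rho of 0.82 (permutation p = 2e-05) over the 20 chromosomes, and r was 0.86 without chromosomes X and 2. Densities over the autosomes, a comparison added after the data were seen which take chromosome length into account, were less closely related (r = 0.54, permutation p = 0.0167; rho = 0.62, permutation p = 0.00545; r = 0.73 without chromosomes 19 and 11). In a family of 7 relations over chromosomes the Benjamini-Hochberg adjusted values of these rho were 0.00014 for numbers and 0.00763 for densities, and those of r were 7e-05 and 0.0234. Autosomes held 9.88 peaks per Mb (chromosome 7) to 14.4 (chromosome 19) in replicate 1 and 3.79 (chromosome 7) to 6.48 (chromosome 10) in replicate 2.

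Notch2 peaks were sparse on the X chromosome in both replicates. The X chromosome held 365 peaks in replicate 1, or 2.28 per Mb against 11.8 on the autosomes, a ratio of 0.193 (95% exact interval 0.174 to 0.214). In replicate 2 it held 161 peaks, or 1.00 per Mb against 5.18, a ratio of 0.194 (0.165 to 0.226). Among shared peaks of replicate 1 the ratio was 0.197 (0.163 to 0.235). On the X chromosome 75.8% of the replicate 2 peaks were shared, close to the share of 75.5% over all chromosomes. The spans between the outermost peaks served as chromosome lengths.

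The excess of peaks in replicate 1 was not the same on every autosome. Chromosome 11 had 3.09 times as many peaks in replicate 1 as in replicate 2 (95% exact interval 2.80 to 3.41), with 1693 against 548. Chromosome 10 had 1.99 times as many (1.83 to 2.17), with 1629 against 818. The ratio varied between the 19 autosomes by more than counting error (chi-square 112, permutation p = 1e-05, with peaks treated as independent although many are clustered). The share of replicate 1 peaks found in replicate 2 was 24.6% on chromosome 11 (95% Wilson interval 22.6 to 26.7%) and 38.1% on chromosome 10 (35.7 to 40.4%), whereas the share of replicate 2 peaks found in replicate 1 was 76.6% and 76.0%. With the replicate 2 shares alike, the difference in the replicate 1 shares restates the ratio of peak numbers.

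**Figure D4:**
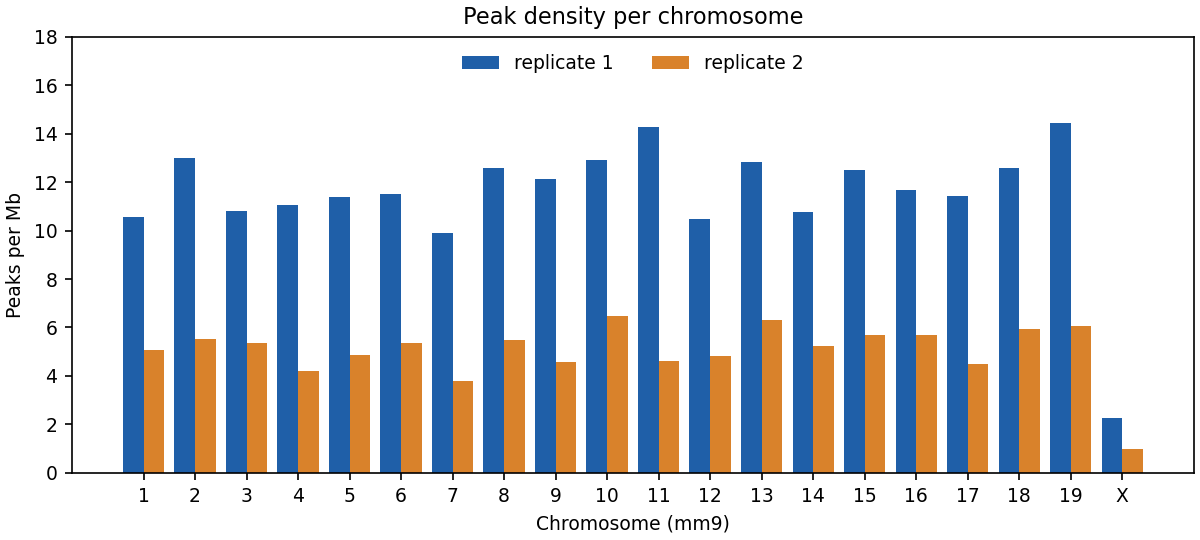
Peaks per Mb (vertical axis) on each chromosome of the mm9 genome (horizontal axis) in replicate 1 and replicate 2, as bars from 0. Both replicates show their lowest density on the X chromosome, with 2.28 and 1.00 peaks per Mb, and replicate 1 is above replicate 2 on every chromosome.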

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

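The alternatives by place in the list, with repeated rows counted, with other distances for joining, for peaks per Mb, for the X chromosome and for gene density were chosen after the data were seen. The excess of the overlap over random placement kept its direction and its side of the threshold in all 10 alternatives, at 19.7 to 188 times the placements. The number and the share of shared replicate 2 peaks moved with the criterion. Overlap of 50% of both peaks left 66.0%, centres within 100 bp left 5540 peaks (44.0%), widening by 500 bp gave 77.0%, and leaving out clusters of 5 or more peaks gave 70.3%. The upper 50% by width held 14325 and 6292 peaks by construction, with 4172 shared (66.3%). The first 50% in list order had 5024 shared (79.8%). Lists of the same number had 5845 shared by width (46.4%) and 55.7% by list order. The density on the X chromosome relative to autosomes was 0.167 in the upper 50% of replicate 1 by width, and 0.161 and 0.146 in the first 50% of replicates 1 and 2 in list order. Clusters of 5 or more shared peaks numbered 2 at 5 kb and 99 at 25 kb, fewer and more by construction. Clusters were left out of each list by itself, which removed 2080 peaks of replicate 1 and 362 of replicate 2. Kept replicate 2 peaks could thereby lose their counterpart by construction. The cause of the remaining shifts was not tested. The difference in recovery between classes and the correlations over peaks and chromosomes kept direction and threshold in every alternative run. With 1 list per replicate, leaving out a replicate leaves no overlap to measure. No paired analysis was possible because a single group of samples had peak lists. The alternatives for promoters, gene lists and motifs were not run for want of an mm9 annotation. Unknown read depth limits any statement on peaks found in 1 replicate, which may be below the threshold of the other. The share rose from 46.4% by width, or 55.7% by list order, to 75.5% with the longer list. A longer list can only raise it, so this rise does not test such a threshold.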

Other observations

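The relations of gene density to peak densities and to the ratio of the replicates, every test by list order and the values for repeated rows were chosen only after the data had been seen. The tests of width-adjusted recovery, of the X chromosome by width and by gene number, and of the 10 kb shift were set before the values they measure were known.

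The excess of replicate 1 peaks tended to be higher on gene-rich autosomes. Chromosome 11, with 13.6 protein-coding genes per Mb, had 3.09 peaks in replicate 1 for each in replicate 2, and chromosomes 9, 4, 7 and 17 followed with 2.64, 2.63, 2.60 and 2.54, at 9.99, 8.71, 13.6 and 11.6 genes per Mb. Chromosome 19, with 12.2 genes per Mb, had 2.39. Chromosomes 10, 3, 13, 14 and 16 had 1.99, 2.01, 2.04, 2.05 and 2.05, at 7.93, 6.34, 7.12, 7.36 and 7.19 genes per Mb. Replicate 1 density itself was not clearly related to gene density (r = 0.33, permutation p = 0.168; rho = 0.30, permutation p = 0.204, adjusted 0.204), and without chromosomes 7 and 11 r was 0.52 and rho 0.45 (permutation p = 0.0732). That of replicate 2 was not either (r = -0.45, permutation p = 0.0513; rho = -0.39, permutation p = 0.101, adjusted 0.118), and its values rested on the same chromosomes, since without them r was -0.16 and rho -0.17 (permutation p = 0.515).

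The ratio of the replicates rose with gene density over the 19 autosomes (rho = 0.79, permutation p = 0.00013, adjusted 0.000455; r = 0.82, permutation p = 3e-05, adjusted 7e-05), and without chromosomes 7 and 11 r was 0.72. The relation remained in the upper 50% by width (rho = 0.78) and in the first 50% in list order (rho = 0.68). With all genes counted in place of protein-coding genes, rho was 0.66. Recovery of replicate 1 peaks adjusted for width fell with gene density (rho = -0.78, permutation p = 0.00021, adjusted 0.00049), and without chromosomes 7 and 11 rho was -0.72. This passed the bound set in advance against a uniform loss of weak peaks in replicate 2. The test cannot decide on such a loss, because the adjustment moved little and recovery without adjustment restates the ratio. The 4 width classes are also coarse. If gene-rich chromosomes only held more weak peaks, lost alike everywhere, the places of their peaks in the list would predict their recovery. They predicted 16.3% of the slope of recovery on gene density (95% bootstrap interval over chromosomes 8.44 to 24.0%). This argues against more weak peaks as the whole cause only as far as list order reflects strength, and the interval leaves out error in that ranking. Within each of 4 classes of list order recovery fell with gene density (rho from -0.81 to -0.72, highest permutation p = 0.00072, highest adjusted 0.00072). These classes are wide, since 69.2% of the first class of replicate 1 were shared but 93.3% of its first 1000 peaks. The mix of weak peaks could therefore still differ between chromosomes within a class. The ratio does not tell a gain of peaks in replicate 1 from a loss in replicate 2, and neither density alone was clearly related to gene density. A candidate explanation is that the replicates differed in the signal captured in gene-rich chromatin, for example at promoters or in GC-rich sequence. GC content, promoters and the handling of the samples were not tested, and a biological difference between the replicates stays open.

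The scarcity of peaks on the X chromosome was alike in both replicates. Few genes on X would leave the number of peaks per gene within the range of the autosomes. Replicate 1 had 0.378 peaks per protein-coding gene on X and 0.726 on chromosome 7, the lowest autosome and the most gene-dense, a ratio of 0.52. Chromosomes 12 and 18 had slightly fewer genes per Mb than X, at 5.77 and 5.83 against 6.02. They held 10.5 and 12.6 replicate 1 peaks per Mb against 2.28 on X, and 4.82 and 5.94 in replicate 2 against 1.00. These values argue against gene number as the cause. A lower copy number of X in tissue of mixed or male sex may thin the weak peaks. The X share was 0.922% in the widest class and 1.40% among the 500 bp peaks, a ratio of 0.657 (95% interval 0.489 to 0.882), below the bound set in advance against this explanation. That bound was wrong in design, since lower coverage also narrows peaks and moves them out of the widest class, so copy number cannot be told apart from a lower binding on X, and mappability was not tested.

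The overlap of the replicates might have come from broad domains that are dense in peaks in both lists without common sites. After a shift of the whole replicate 2 list by 10 kb, the number of overlapping peaks, shared before the shift or not, was 6.44% of the unshifted number, which argues against it. This number was nevertheless 2.90 times the mean of random placements, and at 100 kb the overlap was 1.75 times that mean.

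Peaks listed more than once were wider than the rest. In replicate 1 the 237 such peaks had a median width of 1854 bp against 636 bp for those listed once, and in replicate 2 the 440 such peaks had 1416 bp against 625 bp. The 15 shared regions named by width were all listed more than once in replicate 2, and 4 of them in replicate 1.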
